A study of Mus musculus with 12 samples.

How the data were processed

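Poly(A) RNA of sorted mouse DP and CD4 thymocytes, WT or with a tamoxifen-induced Satb1 knockout, was sequenced as paired reads from TRIzol extracts, per the labels' protocols. The gates of the sorts are not given in the sources used here. The authors deposited 2 tables of raw read counts per gene, 1 for DP and 1 for CD4, each with 6 libraries, and each library was placed in its group by the sample title. The submitters' processing notes name the genome build mm10, Subread 1.0.1, DESeq2 and R 4.1.5, with no role for each. The header of the DP table has the layout that featureCounts of Subread writes. The aligner, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies can lose or share reads, so such genes are reported as uncertain. Gene symbols are those of the tables, and the same 49997 genes were in both. Coordinates are those of the DP table, in mm10. Every column of per-library values was used.

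The counts as deposited were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Each comparison was fitted with edgeR's quasi-likelihood test after TMM normalization and edgeR's default low-count filter, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Unless another test is named, every adjusted p of a gene comes from this test. The DP and CD4 comparisons of KO with WT each used the 6 libraries of 1 table, the comparison of WT cells used the 6 WT libraries, and the interaction, the KO effect in CD4 minus that in DP, used all 12 libraries. CPM are counts scaled by the TMM-adjusted library size to a common total, except those of the sex-linked transcripts, which use the total count. A count of 3 set the limit of detection, which lay between 0.0481 and 0.132 CPM. The limit of detection covers counting error only, and takes no account of PCR copies, which are not independent molecules. The SD and SE given take in the spread between libraries. Principal components used log2 CPM with a pseudocount of 0.5 over the 1000 most variable genes. Standard errors were taken as the log2 fold change divided by the square root of the F statistic.

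Before the data were examined, 28 gene lists were fixed, and 24 of them had at least 3 tested members. They cover DP stage genes, the response to and the components of T cell receptor signalling, the CD4 and CD8 lineages, maturation and egress, regulatory, innate-like and DN (double-negative) thymocyte genes, transcription factors, chemokine and cytokine receptors, the MHC class I pathway, genome organisers, cell cycle, p53 targets, interferon-stimulated and immediate early genes, ribosomal and mitochondrial genes, receptor gene segments, sex-linked transcripts, and markers of B cells, myeloid cells, stroma and erythroid cells. A gene can be on more than 1 list. Each list was tested with camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. None of the 9 lists called in DP or the 8 called in CD4 in KO against WT passed with an estimated correlation. The pattern for mitochondrial genes met only 2 genes of the tables, and that for ribosomal protein genes took in pseudogenes, so 2 lists were added after the data were seen. Of the DP against CD4 overlap, each direction was tested with Fisher's exact test.

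The genes named were also chosen by a rule fixed before the data were examined: Satb1; the 8 with the largest and the 8 with the smallest log2 fold change among called genes with an average log2 CPM of at least 2 that moved the same way in all 3 same-numbered pairs; and up to 3 members of each list with the smallest adjusted p. For the interaction the 5 largest and 5 smallest were taken and for the WT comparison 6 and 6, with the same limits but without the pairs. Symbols of predicted genes were left out. Not every gene the rule gave is named, and some are not reported here. Genes outside the rule in the comparison where they stand (Rag1, Cd8a, S1pr1, Zbtb7b, Ccr7 and Cd40lg in DP; Rag1, Rag2, Cd8a, Ptcra, Il7r, Itgb7, S1pr1, B2m, Gata3, Il4ra, Ccr9 and Cd40lg in CD4; the 4 genes given first for the interaction; Satb1 in the WT comparison) were named by another part of the rule or chosen after their values were seen. Interaction values in the closing part are those of the genes named in the KO comparisons that also passed the interaction test and of the 7 named only as its extremes, and only these were followed under the alternatives.

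The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean count of at least 10, 1 model over all 12 libraries, the replicate number as a block, a minimum absolute log2 fold change of 1, and each library left out in turn. The replicate number equals the batch label, so it was taken to pair the samples. The check of the pairing from the counts, the correlation over genes of the deviations of same-numbered KO and WT libraries from their group means, gave 0.01, -0.04 and 0.2 in DP and 0.14, 0.23 and 0.4 in CD4. Libraries with different numbers gave -0.17 to 0.22 in DP and -0.31 to 0.23 in CD4, so the pairing rests on the labels, and these correlations do not single out the same-numbered pairs of replicates 1 and 2. The erythroid markers Hba-a1 and Hba-a2, near-identical genes, did follow the number: both stood highest in replicate 2 and lowest in replicate 3 in all 4 groups. Values with the block are given only where the block changed a call or moved a count by over 1.5 times.

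The fits were tested on simulated counts with the means and library sizes of the real data and planted changes of 1.5, 2 and 4 times. Of the planted genes 47.8%, 65.6% and 90.8% were recovered for DP KO against WT (16776 genes simulated), 47.6%, 67.2% and 96.8% for CD4 KO against WT (17316 genes), 47.6%, 81.5% and 90.3% for CD4 WT against DP WT (17404 genes) and 15.4%, 37.9% and 70.3% for the interaction (18467 genes). Of the calls 6.3%, 5.6%, 10.9% and 0% were not planted, in the same order. All recovered genes had the planted direction. The rows of the T cell receptor segments (130 alpha V, 60 alpha J and 35 beta V) and of Trdc and Ighm held 0 counts in every library and were not tested, so the receptor repertoire was not measured here.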

Results

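The study sequenced poly(A) RNA from sorted mouse thymocytes of 2 kinds, each from wild-type (WT) thymus and from thymus with a tamoxifen-induced knockout (KO) of Satb1. SATB1 is a nuclear protein that binds DNA and organises chromatin in T cells. DP thymocytes carry both co-receptors, CD4 and CD8, and are the stage at which the T cell receptor alpha chain is rearranged and cells are selected. CD4 thymocytes are a later stage that has kept CD4. All 12 libraries, WT included, are labelled as tamoxifen-treated, and each of the 4 groups holds 3 libraries with a batch number equal to the replicate number. Total counts ran from 22790504 in DP WT replicate 3 to 62422640 in CD4 KO replicate 2. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, part of which may be technical. Most libraries held transcripts of both sexes, as given below, so a library need not stand for a single mouse. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 15.2 to 50.8, and all 12 were kept as separate samples. Levels are in CPM (counts scaled to library size), mean ± SD over the 3 libraries of a group, and log2 fold changes are given ± SE.

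**Figure D1:**
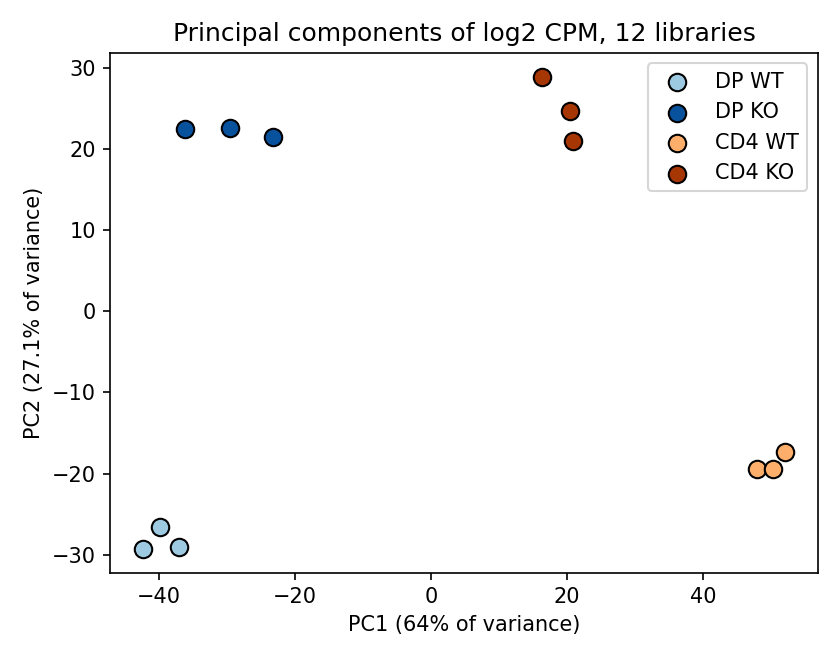
Principal components of log2 CPM over the 1000 most variable genes, 1 point per library, coloured by group. The first component held 64% of the variance and parted DP from CD4, and the second held 27.1% and parted KO from WT in both cell types.

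Satb1 itself (chromosome 17, 51736187 to 51833290 of mm10, minus strand) was counted in every library. In DP cells it stood at 3867 ± 29.1 CPM in WT and 2609 ± 231 CPM in KO, a log2 fold change of -0.56 ± 0.08 (adjusted p = 0.000299). In CD4 cells it fell from 3273 ± 258 to 1499 ± 40.7 CPM, a log2 fold change of -1.13 ± 0.08 (adjusted p = 4.02e-06). The KO libraries were lower than all WT libraries of their cell type, 2460 to 2870 against 3830 to 3890 CPM in DP and 1470 to 1550 against 3000 to 3520 CPM in CD4. The labels do not say which part of the gene was deleted, and a count over the whole gene takes in reads from exons that were left, so these values check the direction of the genotype labels and not the extent of the deletion.

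**Figure D2:**
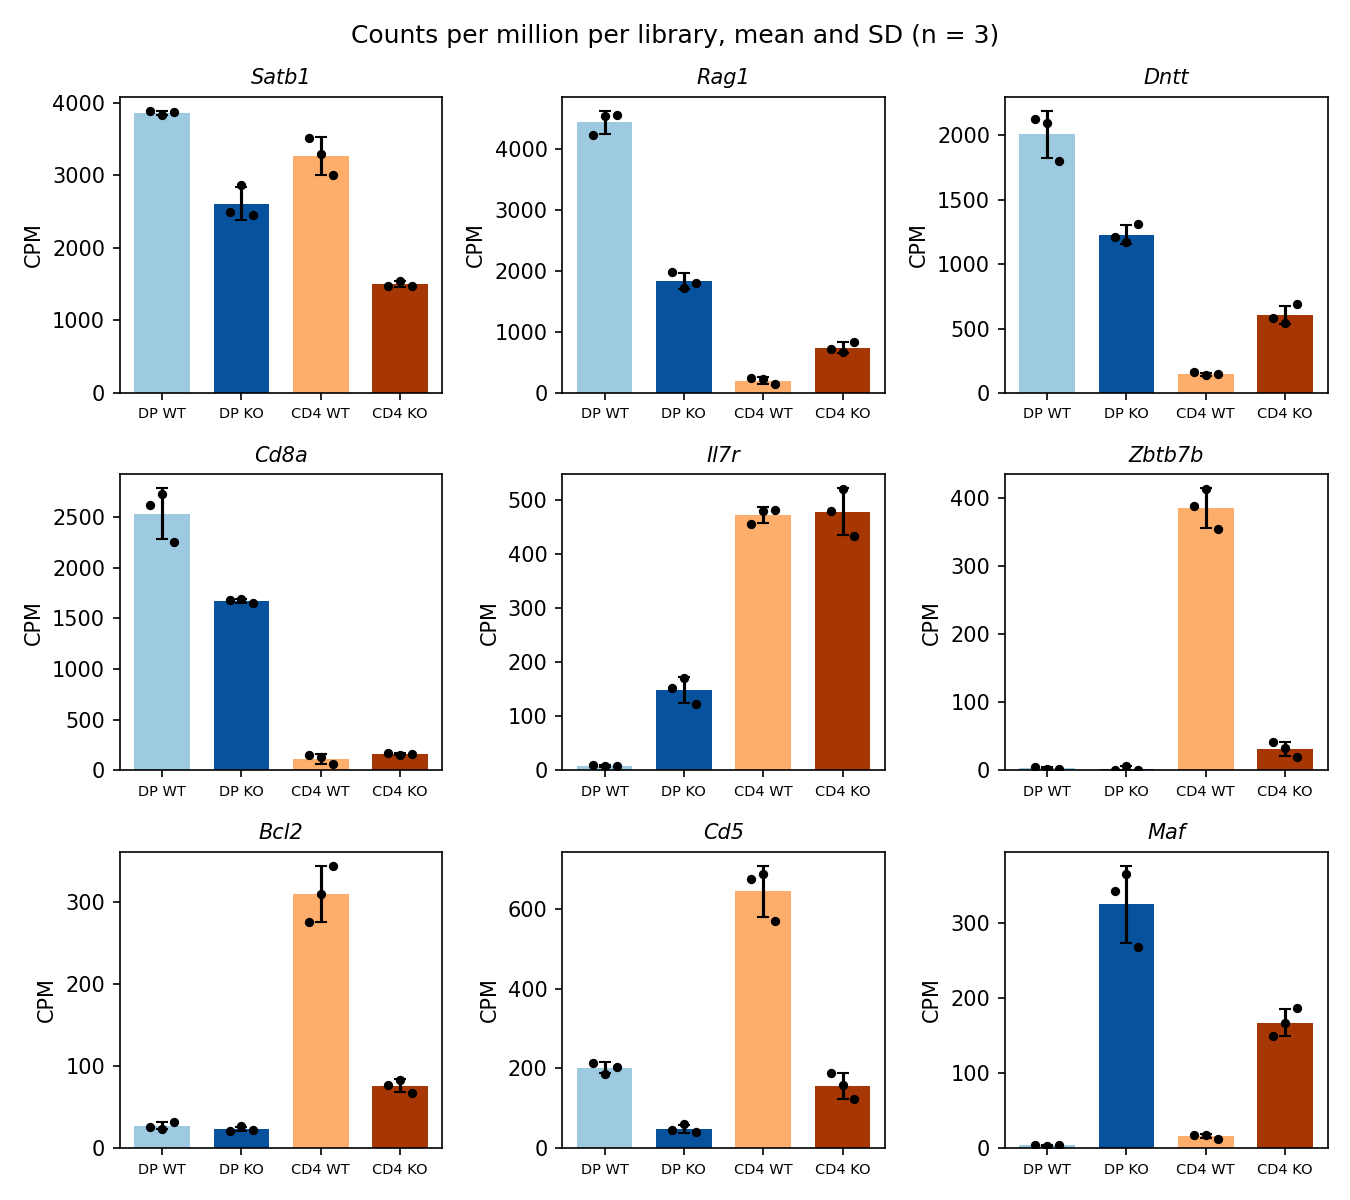
CPM of 9 genes in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of each group. Rag1 and Dntt were higher in CD4 KO than in CD4 WT, Il7r rose in DP KO, Zbtb7b and Bcl2 fell in CD4 KO, and Maf rose and Cd5 fell in both cell types. Cd8a did not pass the test in CD4 (adjusted p = 0.328).

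The first comparison asked what the induced loss of Satb1 changed in DP thymocytes. Most genes of the DP stage list fell, among them both recombinase genes, while some genes used by mature and effector T cells rose. Rag1, which with Rag2 cuts antigen receptor genes, fell from 4445 ± 185 to 1842 ± 128 CPM, and Rag2 from 208 ± 11.5 to 50.3 ± 4.16 CPM. Il2ra, the alpha chain of the interleukin-2 receptor, rose from 12.5 ± 5.59 to 407 ± 49.2 CPM, and Il7r, the interleukin-7 receptor, from 8.33 ± 1.75 to 149 ± 23.5 CPM. Gzma, a granule protease of killer cells, rose from 27.3 ± 4.93 to 235 ± 14.1 CPM. In total 2811 genes were higher and 2368 lower in DP KO among 16776 tested, of which 856 and 1153 had an absolute log2 fold change of at least 1.

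The DP genes with the largest rises, picked by size among genes that moved the same way in all 3 same-numbered pairs, were mostly close to silent in WT. Necab1, a calcium-binding protein gene (chromosome 4, 14952245 to 15149804, minus strand), went from 0.192 ± 0.0535 to 50.3 ± 2.88 CPM, a log2 fold change of 8.02 ± 0.17 (adjusted p = 4.96e-10). Maf, a transcription factor of helper and innate-like T cells (chromosome 8, 115703253 to 115706894, minus strand), went from 3.32 ± 0.690 to 325 ± 50.9 CPM, a log2 fold change of 6.65 ± 0.20 (adjusted p = 1.05e-07). The others were Actn2 (6.38), Sdc1 (6.27), Scin (6.20), Ankrd35 (5.92) and Thbs2 (6.74), with log2 fold changes in parentheses. Thbs2 stood at 36 CPM in DP KO replicate 3 against 7.76 and 7.96 in the other KO libraries, and its call was lost when any 1 WT library was left out (adjusted p = 0.0614 to 0.0779) and with limma-voom (0.17). Ankrd35 was at 0 CPM in DP WT replicate 3. The largest fall was in Hspg2, the basement membrane proteoglycan perlecan, from 15.6 ± 0.819 to 0.372 ± 0.243 CPM with a log2 fold change of -5.31 ± 0.36 (adjusted p = 8.19e-06). Nron (-4.72) and Jup (-4.59) came next, then Slc7a11, the cystine transporter, from 172 ± 13.4 to 8.03 ± 0.544 CPM with -4.41 ± 0.09 (adjusted p = 4.96e-10). Podxl2 (-4.37), Rbm24 (-4.19), Cacna1e (-4.00) and Smoc1 (-3.96) followed.

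Of the 13 DP stage genes, 10 were lower and 1 was higher in DP KO, with the same counts adjusted over the list alone. Besides Rag1 (log2 fold change -1.26 ± 0.08) and Rag2 (-2.03 ± 0.08), Ptcra, the surrogate alpha chain of the pre-T cell receptor, fell by 2.53, and Ets2 by 1.91, the last uncertain because the annotation places further exons of this gene on other sequences. As a list the DP stage genes were lower than other genes (camera, adjusted p = 2.31e-06; adjusted p = 0.127 with an estimated correlation). Components of T cell receptor signalling were also lower, 12 of 18 against 3 higher (3 higher and 13 lower adjusted over the list alone). Cd6 fell by 1.46, Cd28, uncertain for the same reason as Ets2, by 1.01 and Cd3d by 0.86 on the log2 scale (list adjusted p = 0.000279; 0.765 with an estimated correlation, again an adjusted p). Both co-receptors fell in DP KO: Cd8b1 by 1.11, Cd8a by 0.58 and Cd4 by 0.51. The call of Cd8a was lost in 1 model over all 12 libraries (-0.60, adjusted p = 0.106). Cd5, whose product dampens receptor signalling, fell from 202 ± 14.2 to 48.2 ± 10.2 CPM, whereas Pdcd1, which encodes the inhibitory receptor PD-1, rose from 8.33 ± 1.53 to 32.8 ± 8.55 CPM.

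Among 14 maturation and egress genes 7 were higher and 1 was lower in DP KO, also adjusted over the list alone. Il7r rose by 4.16 ± 0.18 (adjusted p = 7.32e-07), the integrin gene Itgb7 by 2.41 ± 0.12 and S1pr1, the receptor that guides exit from the thymus, by 2.51 ± 0.27. The list's adjusted p was 0.0379, and the adjusted p was 0.765 with an estimated correlation. The CD8 lineage and cytotoxic list had 9 higher and 3 lower of 17 (10 and 3 adjusted over the list alone), with an adjusted p of 0.0344 and an adjusted p of 0.765 with an estimated correlation. Its risers included the granzyme genes Gzma (3.12) and Gzmb (3.59, from 0.486 ± 0.0476 to 5.74 ± 1.97 CPM), whereas the CD8 co-receptor genes were among those that fell. In the MHC class I pathway 8 of 14 rose and 0 fell, also adjusted over the list alone (list adjusted p = 0.0159, and adjusted p = 0.765 with an estimated correlation). B2m, the invariant light chain, rose from 201 ± 20.6 to 593 ± 32.3 CPM. Psmb9 rose by 0.50, a value that is uncertain because the annotation places further copies of this gene on alternative sequences. DP KO replicate 2 also had more of 3 transcripts of CD4 cells than the other DP KO libraries: 7.13 CPM of Zbtb7b, 8.19 of Ccr7 and 2.46 of Cd40lg, against 0.254 to 1, 1.92 to 2.5 and 0.347 to 0.509. The DP WT libraries had 2.41 to 5.32, 6.29 to 9.39 and 0.903 to 1.14 CPM. Replicate 2 thus lay above them for Zbtb7b and Cd40lg and within their range for Ccr7. KO replicates 1 and 3 lay below them for all 3 genes. Without DP KO replicate 2 the adjusted p of the list was 0.0879 for maturation, 0.0671 for the CD8 list and 0.0671 for MHC class I, and without DP WT replicate 3 that of the CD8 list was 0.0626.

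Cytokine receptor genes split, with 9 higher and 6 lower of 16, also adjusted over the list alone. Il18r1 rose by 5.67 ± 0.14, Il2ra by 5.07 ± 0.37 and Ifngr1 by 2.13 ± 0.08, from 421 ± 29.0 to 1827 ± 41.7 CPM, and Il4ra fell by 1.60 ± 0.07. The list as a whole did not pass (adjusted p = 0.0766), but did with the replicate number as a block (0.0402). In the innate-like and gamma-delta list, which holds Maf, Il18r1 and Il17rb, 5 of 10 tested members were higher and 1 was lower (5 and 2 adjusted over the list alone), with an adjusted p of 0.0628 and, with the block, 0.0355. Ribosomal protein genes showed a small common rise: 69 of 84 protein-coding members were higher and 0 lower (76 and 0 adjusted over the list alone), with a median log2 fold change of 0.38 and Rps2 at 0.58. The list as fixed, which also takes in pseudogenes with uncertain counts, had 115 higher and 7 lower of 230 (126 and 8 adjusted over the list alone), with an adjusted p of 2.09e-11 and an adjusted p of 0.765 with an estimated correlation. Rpl10a, at 0.60, has such copies.

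Cell cycle genes in DP KO had 5 lower and 0 higher of 23 (3 and 0 adjusted over the list alone), Cdc20 at -0.48 among them. Genome organisers had 5 lower and 0 higher of 13, also adjusted over the list alone, with Hmgb1 at -0.36. The adjusted p was 0.00759 for the cell cycle list and 0.0106 for the organisers, with an adjusted p of 0.765 for each with an estimated correlation. Neither passed without DP KO replicate 2 (0.166 and 0.0879). Of the interferon-stimulated genes 5 of 16 were higher and 0 lower (6 and 0 adjusted over the list alone). The list's adjusted p was 0.00271, and the adjusted p was 0.765 with an estimated correlation. With the block 0 of the 16 passed as single genes, while the list still passed camera as higher (adjusted p = 0.000124). Oas1a, at 1.80, then had an adjusted p of 0.0812 (0.0696 with limma-voom), and it ranged over 4.23 to 12.3 CPM between the DP KO libraries. Its call was also lost without DP WT replicate 1 (adjusted p = 0.0659) and without DP WT replicate 2 (0.0617). DP WT replicates 1 and 2 had 0.829 and 0.269 CPM of Xist, the transcript that silences 1 X chromosome in females, against 194 to 588 CPM in the other 10 libraries. Those 10 also had 39.4 to 121 CPM of Ddx3y, on chromosome Y, so they held transcripts of both sexes. Whether they were pools of mice was not tested. DP KO and DP WT thus differed in sex composition. With DP WT replicate 3 as the lone control, a choice made after seeing the data, 1159 genes were higher and 877 lower, and Psmb9, Cdc20, Hmgb1, Oas1a and Thbs2 were not called (adjusted p = 0.0613, 0.165, 0.185, 0.288 and 0.279).

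The second comparison put the same question to CD4 thymocytes, and several lists moved as a whole against their direction in DP, in part through other members. Genes of the DP stage were mostly higher in CD4 KO, every cell cycle gene on the list was higher, and most of the maturation and egress genes were lower. Rag1 rose from 200 ± 53.4 to 743 ± 87.9 CPM and Dntt, the terminal transferase that adds bases at receptor gene joints, from 147 ± 11.8 to 605 ± 73.2 CPM. Zbtb7b, which encodes ThPOK, the regulator of CD4 lineage choice, fell from 386 ± 29.4 to 31.5 ± 10.8 CPM. In total 3620 genes were higher and 3248 lower among 17316 tested, 1424 and 968 of them with an absolute log2 fold change of at least 1.

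The largest rises in CD4 KO were in Necab1, from 0.0559 ± 0.0968 to 26.8 ± 7.42 CPM, with a log2 fold change of 9.39 ± 0.61 (adjusted p = 2.32e-05), and in Nyap2 (5.84), Greb1 (5.82), Gpr82 (5.62), Sdc1 (5.61), Lpar4 (5.59) and Hlf (5.40). Necab1 had counts in only 1 CD4 WT library, so its fold is imprecise. The largest falls were in Klra9 (-5.83), Tmie (-4.98), Gpnmb (-4.77), Pyroxd2 (-4.74), Slc15a1 (-4.71), Prlr (-4.71), Als2cl (-4.46 ± 0.74, adjusted p = 0.00913) and Tspan9 (-4.41). Als2cl went from 667 ± 56.9 to 30.2 ± 19.6 CPM, with 43.9, 38.9 and 7.71 CPM in KO replicates 1, 2 and 3. Klra9 belongs to a family of near-identical genes and its counts are uncertain.

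Of the 13 DP stage genes 10 were higher and 2 lower in CD4 KO, also adjusted over the list alone (list adjusted p = 3.69e-05, and adjusted p = 0.494 with an estimated correlation). Aqp11 rose by 2.57 ± 0.10, Dntt by 2.05 ± 0.10, Arpp21 by 1.90 ± 0.09, Rag1 by 1.89 ± 0.21, Cd8b1 by 1.38, Rag2 by 1.22 and Ptcra by 1.19. Cd8a was the member that did not pass, at 161 ± 7.77 CPM in KO and 115 ± 46.6 CPM in WT (adjusted p = 0.328). The 23 cell cycle genes all rose, also adjusted over the list alone, with a median log2 fold change of 1.49 (list adjusted p = 3.17e-14, and adjusted p = 0.622 with an estimated correlation). Ccnb1, a mitotic cyclin, rose from 24.7 ± 4.18 to 90.5 ± 9.32 CPM, Aurka by 1.71 and Cdc6, which licenses replication origins, by 1.51. Among 13 genome organisers 8 were higher and 1 was lower (9 and 1 adjusted over the list alone, 10 and 2 with the block), with Hmgb2 at 1.63 and Lmnb1 at 1.10 (list adjusted p = 0.00445, and adjusted p = 0.802 with an estimated correlation). The abundance of several of these genes is tied to the cell cycle.

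Of 14 maturation and egress genes 9 were lower and 1 was higher in CD4 KO, also adjusted over the list alone (list adjusted p = 0.000168, and adjusted p = 0.622 with an estimated correlation). Bcl2, the survival factor, fell from 310 ± 34.7 to 75.8 ± 7.77 CPM, and the chemokine receptor gene Ccr7 from 343 ± 17.0 to 37.8 ± 11.6 CPM. Other members did not pass the test: Il7r was at 478 ± 43.8 CPM in KO and 472 ± 13.9 CPM in WT (adjusted p = 0.879), S1pr1 at 158 ± 11.6 and 172 ± 5.57 CPM (0.175) and Itgb7 at 355 ± 7 and 369 ± 26.7 CPM (0.579). In the MHC class I pathway 10 of 14 were lower and 0 higher (10 and 1 adjusted over the list alone, 10 and 2 with the block), with an adjusted p of 0.000142 and an adjusted p of 0.622 with an estimated correlation. H2-K1 fell by 1.16 and H2-D1 by 0.90, both from a family of similar genes that can share reads, while B2m, at 926 ± 14.3 CPM in KO and 1033 ± 95.7 CPM in WT, did not pass (adjusted p = 0.146). The members of both lists named as falling in CD4 were not called in DP KO: Bcl2 (-0.20, adjusted p = 0.283), Ccr7 (-0.83, 0.358), H2-K1 (0.48, 0.224) and H2-D1 (-0.17, 0.556). These named genes therefore did not reverse a called change in DP. The CD4 lineage list had 5 lower and 2 higher of 9 (6 and 2 adjusted over the list alone) and did not pass as a list (adjusted p = 0.103). Zbtb7b fell by 3.61 ± 0.28 (adjusted p = 0.000161), Cd40lg, which encodes the ligand by which helper cells activate B cells, by 2.40 ± 0.22 and Cd4 by 0.76 ± 0.09. Myb rose by 1.74 and Gata3 by 0.45.

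T cell receptor signalling components were lower in CD4 KO for 15 of 18 and higher for 2, also adjusted over the list alone (list adjusted p = 1.35e-06, and adjusted p = 0.494 with an estimated correlation), with Cd6 at -1.73 and Fyn at -0.95. The response genes of that receptor had 9 lower and 2 higher of 14 (10 and 3 adjusted over the list alone), with an adjusted p of 0.0241 and an adjusted p of 0.622 with an estimated correlation. Itm2a fell from 996 ± 24.6 to 163 ± 19.3 CPM and Cd5 from 645 ± 64.5 to 155 ± 33.2 CPM, whereas Pdcd1 rose from 38.1 ± 4.69 to 184 ± 27.9 CPM. The regulatory T cell list went both ways, with 5 higher and 8 lower of 16, also adjusted over the list alone: Il2ra rose by 2.76 and Ikzf2, which encodes Helios, by 1.59, while Ikzf4 fell by 1.41 (list adjusted p = 0.496). Of the cytokine receptors 6 were higher and 8 lower of 16 (6 and 9 adjusted over the list alone), with Ifngr1 at 3.08, Il18r1 at 2.00 and Il10ra at 1.70 against Il6ra at -2.44 and Il4ra at -1.63 (list adjusted p = 0.42). The homing receptor genes Ccr8 (-2.64) and Ccr9 (-2.12) fell, in a list with 4 higher and 5 lower of 16 and an adjusted p of 0.587. Interferon-stimulated genes were lower for 9 of 16 and higher for 0 (11 and 0 adjusted over the list alone, 5 and 0 with the block), Ifit2 at -0.52 among them, with an adjusted p of 0.000398 and an adjusted p of 0.803 with an estimated correlation.

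**Figure D3:**
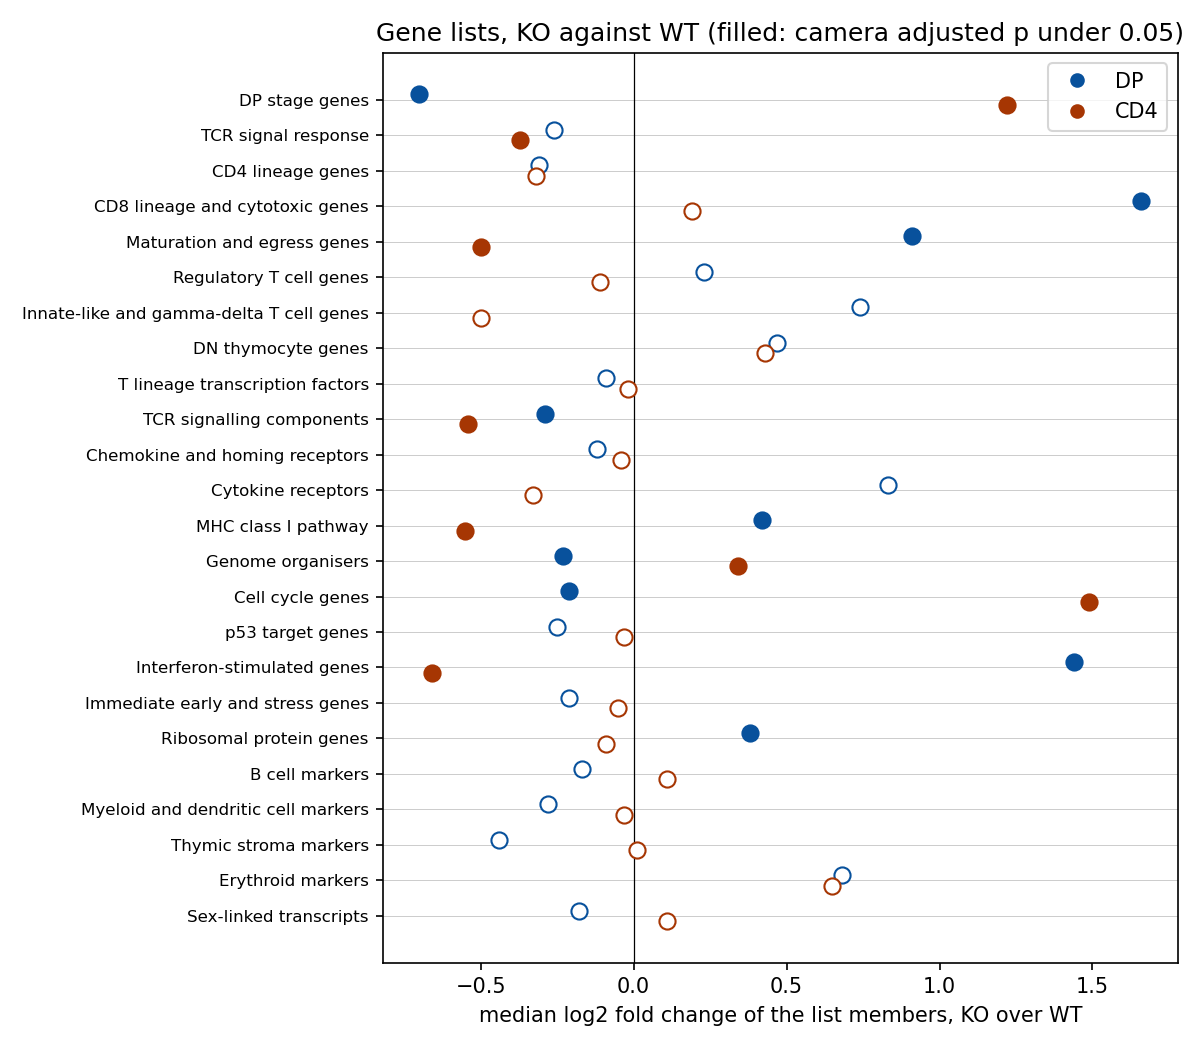
Median log2 fold change of KO over WT for each of the 24 gene lists tested, in DP and in CD4. Filled points have a camera adjusted p under 0.05, 9 in DP and 8 in CD4, none of which passed with an estimated correlation. The DP stage genes had medians of -0.70 in DP and 1.22 in CD4, and the cell cycle genes of -0.21 and 1.49.

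The third comparison asked which effects of the KO were shared by the cell types and which differed. Among 16125 genes tested in both, 1215 were higher in KO in both cell types, against 609 expected of independent lists (Fisher's exact test, two-sided, adjusted p = 3.4e-180), and 819 were lower in both, against 393 expected (adjusted p = 1.07e-122). Opposite calls were fewer than independent lists would give: 388 genes were higher in DP and lower in CD4 (529 expected, adjusted p = 1.93e-14) and 329 were lower in DP and higher in CD4 (453 expected, adjusted p = 4.23e-13). Genes are not independent replicates, so these p-values are too small. Same-numbered DP and CD4 libraries may also share an animal or batch. The overlap test leaves this out, and the interaction takes it in only with the replicate block. In WT replicates 1 and 2, Xist stood at 0.829 and 0.269 CPM in DP but at 330 and 285 CPM in CD4. Those same-numbered libraries thus did not hold the same mix of sexes. The correlation of the log2 fold changes across genes was 0.43 (Pearson) and 0.26 (Spearman). Maf, Necab1 and Sdc1 rose and Cd5, Cd6, Il4ra and Fas fell in both.

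**Figure D4:**
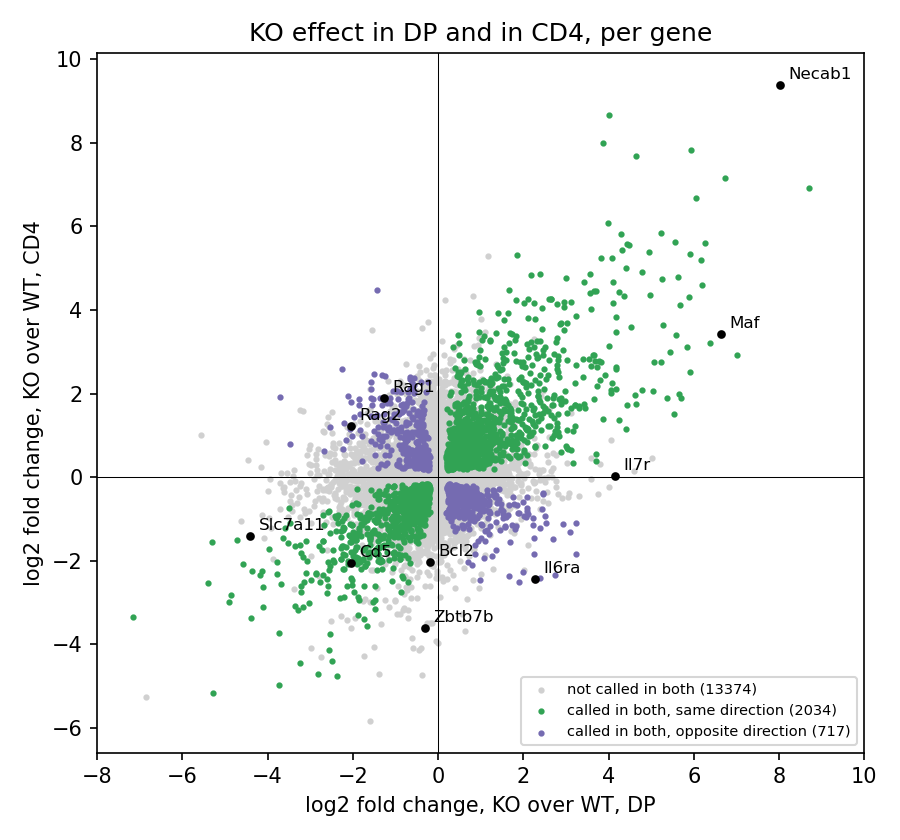
Log2 fold change of KO over WT in CD4 against that in DP, 1 point per gene tested in both. Green points, 2034 genes, were called in both in the same direction, and purple points, 717 genes, in opposite directions, Rag1 and Rag2 (lower in DP, higher in CD4) and Il6ra (higher in DP, lower in CD4) among them.

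The difference between the effects was tested as an interaction over all 12 libraries, in which 5088 of 18431 genes passed, 2634 with a more positive KO effect in CD4 and 2454 with a more negative one. DP KO and DP WT differed in sex composition, as given above. That difference enters the interaction, and its part in these calls was not tested. The interaction log2 value was 3.26 ± 0.15 for Rag2, 3.16 ± 0.23 for Rag1 and 3.74 ± 0.22 for Ptcra, and -4.13 ± 0.20 for Il7r. The extremes were Scn4b (4.26 ± 0.29, adjusted p = 1.06e-07), Hspg2 (3.75 ± 0.64, adjusted p = 0.000751), Il6ra (-4.69 ± 0.29, adjusted p = 1.76e-07), Oas2 (-4.30), Amigo2 (-4.30), Ptgir (-4.26) and Pyroxd2 (-4.32). The call of Pyroxd2 was lost without DP KO replicate 2 (adjusted p = 0.16), without DP WT replicate 2 (0.0606) and with no low-count filter (0.0557). Rn7s2 (3.82), Rn7s1 (3.78) and Rn18s-rs5 (3.77), which derive from 7S and ribosomal RNA with near-identical copies, were as extreme but uncertain. Rn18s-rs5 ranged from 511 to 9030 CPM over the DP libraries, and its call was lost without any 1 of 7 libraries, with adjusted p of 0.0541 to 0.0699. Rn7s1 lost its call without any 1 of 8 (0.0512 to 0.0804) and Rn7s2 without any 1 of 7 (0.0608 to 0.0783). With no low-count filter the calls of Rn18s-rs5, Rn7s1 and Rn7s2 were lost as well (adjusted p = 0.0547, 0.0658 and 0.0636). As lists, the DP stage genes (median 2.50), maturation and egress genes (-1.73), innate-like and gamma-delta genes (-1.87) and cytokine receptors (-0.80) differed also with an estimated correlation (adjusted p = 0.00859, 0.0341, 0.0305 and 0.0354). The MHC class I, genome organiser, cell cycle, interferon and ribosomal protein lists passed only with the preset correlation, with an adjusted p of 0.0993, 0.25, 0.176, 0.176 and 0.481 with an estimated correlation.

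The last comparison set WT CD4 against WT DP cells, as a reference for the direction of maturation. It joined libraries of 2 count tables that were deposited apart, so a difference in counting between the tables cannot be told from cell type. Sex composition differed as well. Xist stood at 0.829 and 0.269 CPM in DP WT replicates 1 and 2, against 285 to 387 CPM in the CD4 WT libraries. The part of sex in this comparison was not tested. Genes of the DP stage were lower in CD4 for 12 of 13 and higher for 0, and all 14 maturation and egress genes were higher, both also adjusted over the list alone. Rag1 fell by 4.47 ± 0.22, Cd8a by 4.46 ± 0.42, and Rag2, Arpp21 and Cd8b1 had log2 fold changes of -4.23, -3.93 and -3.86, while S1pr1 rose by 6.28 ± 0.13, H2-K1 by 4.32 and Itgb7 by 3.74. The CD4 lineage genes Zbtb7b (6.75 ± 0.33), Cd40lg (6.45 ± 0.11) and Lef1 (1.52) were higher in CD4, in a list with 5 higher and 3 lower of 9, and so was Runx3 (2.11, uncertain because of exons placed on other sequences), in a CD8 lineage and cytotoxic list with 13 higher and 3 lower of 16. The adjusted p was 2.45e-11 for the DP stage list and 1.48e-11 for the maturation list, with an adjusted p of 0.111 and 0.16 with an estimated correlation. In total 4860 genes were higher and 4713 lower in CD4 among 17369 tested. The largest differences were in Dcst2 (7.53), Acvrl1 (6.99), Igfbp4 (6.77), Zbtb7b, Cd40lg and St8sia6 (6.41), and, among those lower in CD4, in Rag1, Cd8a, H1f10 (-4.32), Medag (-4.23), Rag2 and BB031773 (-4.22). Dcst2 and Zbtb7b are direct neighbours on opposite strands of chromosome 3, from 89350417 to 89377643 and from 89377644 to 89393673. Without strand, reads that run past the end of Zbtb7b cannot be told from those of Dcst2, so Dcst2 is uncertain. BB031773 lost its call without DP WT replicate 1 (adjusted p = 0.0504), without DP WT replicate 2 (0.0535) or without CD4 WT replicate 1 (0.0578). Satb1 was slightly lower in CD4 (-0.24 ± 0.08, adjusted p = 0.0177), which was lost without DP WT replicate 2 (0.0619) or CD4 WT replicate 2 (0.0505).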

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

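The tests of cells carried over between sorts, of scaling and of the remaining Satb1 counts were chosen, and their bounds set, after the results were seen, and so was the count of paired splits for the interaction. Those of selection, of equal mixing and of other splits of the samples were written before.

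Of 89 genes named for the KO comparisons, 62 had a KO effect that differed between CD4 and DP by the interaction test. Over all genes tested 27.6% did. Many of the 89 were picked by a large change or a small adjusted p in 1 cell type, which favours a difference from the other. The share among the named genes is therefore not read as a result. A further 7 (Scn4b, Amigo2, Oas2, Ptgir, Rn7s1, Rn7s2 and Rn18s-rs5) were picked as extremes of that test and passed it by selection. The values here are interaction log2 values, the effect in CD4 minus that in DP. Among DP stage genes the effect was more positive in CD4: Ptcra 3.74, Rag2 3.26, Rag1 3.16, Arpp21 3.04, Dntt 2.76, Cd8b1 2.5, Aqp11 2.4 and Ets2 1.64, the last with exons placed on other sequences and so uncertain. The same held for cell cycle genes and genome organisers, with Ccnb1 at 2.15, Aurka at 2.09, Cdc20 at 2.03, Hmgb2 at 1.9, Cdc6 at 1.68, Lmnb1 at 1.32 and Hmgb1 at 1.29. Maturation and egress and MHC class I genes had a more negative effect in CD4: Il7r -4.13, S1pr1 -2.6, Itgb7 -2.46, Ccr7 -2.34, Bcl2 -1.82, B2m -1.72, H2-K1 -1.63, Psmb9 -0.72 and H2-D1 -0.71. Single genes from lists that were not called by camera in the interaction (CD4 lineage, TCR signal response, TCR signalling components and T lineage transcription factors, adjusted p = 0.165 to 0.894) were Myb 2.62, Bcl6 1.79, Id2 -1.07, Fyn -1.2, Gata3 -1.22, Itm2a -2.42 and Cd40lg -2.51. Ccr7 and Cd40lg rest on few counts in DP. The call of Ccr7 was lost without any 1 of 7 libraries (adjusted p = 0.0559 to 0.0739) and with no low-count filter (0.064), and that of Cd40lg without any 1 of 9 (0.0753 to 0.112), with the replicate block (0.0727) and with no low-count filter (0.0993). Without DP KO replicate 2 the values were -1.45 for Ccr7, still called (adjusted p = 0.0304), and -1.19 for Cd40lg.

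Single genes from several other lists with a more negative effect in CD4 were Il6ra -4.69, Ptgir -4.26, Il18r1 -3.66, Gzmb -3.63, Ccr8 -3.54, Maf -3.21, Il2ra -2.3, Ikzf4 -2.07 and Il17rb -1.75, and those with a more positive one were Il10ra 1.69, Ikzf2 1.09, Gzma 1.08 and Ifngr1 0.96. The call of Gzma was lost without any 1 of 8 libraries (adjusted p = 0.0551 to 0.083) and with no low-count filter (0.106). Interferon-stimulated genes stood at -4.3 (Oas2) and -2.04 (Oas1a), and ribosomal protein genes at -0.61 (Rpl10a) and -0.44 (Rps2). Satb1 stood at -0.56. Genes picked by the size of their change stood at 4.26 (Scn4b), 3.75 (Hspg2), 3.65 (Cacna1e), 3.2 (Nron), 3 (Slc7a11), 2.96 (Smoc1), 2.52 (Jup), 2.12 (Podxl2), 1.86 (Rbm24), 1.55 (Greb1), -1.6 (Scin), -2.38 (Gpnmb), -3.16 (Actn2), -4.3 (Amigo2) and -4.32 (Pyroxd2). Rbm24 lost its call without CD4 KO replicate 1 (adjusted p = 0.0796) and Gpnmb without any 1 of 5 libraries (0.0532 to 0.158). The RNA genes Rn7s2, Rn7s1 and Rn18s-rs5 stood at 3.82, 3.78 and 3.77, calls that were lost without any 1 of 7, 8 and 7 libraries (adjusted p = 0.0608 to 0.0783, 0.0512 to 0.0804 and 0.0541 to 0.0699) and with no low-count filter (0.0636, 0.0658 and 0.0547). That of Pyroxd2 was lost without DP KO replicate 2 (0.16) or DP WT replicate 2 (0.0606) and with no low-count filter (0.0557). Epcam, a marker of thymic epithelium, stood at 2.05 and the B cell marker Cd79b at 1.74. Over the lists, the median interaction value was 2.5 for DP stage genes, 1.76 for cell cycle genes, 0.5 for genome organisers, -0.44 for ribosomal protein genes, -0.77 for the MHC class I pathway, -0.8 for cytokine receptors, -1.73 for maturation and egress genes, -1.87 for innate-like and gamma-delta genes and -2.02 for interferon-stimulated genes.

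The first pattern weighed is the rise of DP stage and cell cycle genes in CD4 KO. A scaling of the libraries gives all genes 1 shift. The median log2 fold change was 1.22 for the DP stage genes and 1.49 for the cell cycle genes, against 0.002 over all genes. With DESeq2 size factors 0 of their calls ended. These values argue against scaling as the whole cause. By edgeR 8 of the 13 tested DP stage genes and 10 of the 23 tested cell cycle genes differed from the median of their list by more than their spread (adjusted p under 0.05). That form replaced earlier ones with the same reading, and alone it decides little, since 39.7% of all genes were called in CD4. DP KO cells, taken at the mean of their libraries, would have to make up 59% or more of the CD4 KO sort for most of the cell cycle genes. A carried-over subset richer in cell cycle transcripts was not tested. Of 246 abundant genes enriched in DP, 32.9% lay below 59% of their DP KO level. This argues against DP KO cells of mean make-up as the whole cause of the cell cycle part. For the DP stage genes the share needed was 33.1% or more for most members and 249% for Ptcra, which no share of such cells explains, but only 0.813% of the 246 genes lay below it, and Cd8a lay at 9.11% to 10% in the CD4 KO libraries, so that carried-over DP-like cells without Cd8a, which a gate against surface CD8 could let through, and a DP programme kept on in CD4 cells cannot be told apart from gene totals for the other members. An earlier form of this test, with both lists pooled and a bound at the 10th percentile of the enriched genes (43.1%), had counted against carried-over cells for both parts, and was replaced after its result was seen.

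The second pattern is the rise of maturation and MHC class I genes in DP KO, with a smaller difference between CD4 and DP cells in KO than in WT. Scaling is argued against as the whole cause, since the median of the 25 tested members was 0.49 against 0.007 over all genes. With DESeq2 size factors 2 of their calls ended (Slfn2 and Cd55). By edgeR 13 of the 25 differed from their median by more than their spread (adjusted p under 0.05). That form was chosen after 3 earlier ones had left it open, argued against it and left it open again. Alone it decides little, since 30.9% of all genes were called in DP. CD4 KO cells of mean make-up in the DP KO sort are also argued against as the whole cause. Most members needed 10.9% of such cells or more, and 12.7% of 276 abundant genes enriched in CD4 lay below that share. An earlier form set 10.9% beside the 10th percentile of those genes (10.3%) and beside Zbtb7b, Ccr7 and Cd40lg in DP KO replicate 2 (22.6%, 21.7% and 14.2%). It had left this open and was replaced after its result was seen. The same 3 genes lay below 10.9% in replicates 1 and 3 (Zbtb7b 3.18% and 0.806%, Ccr7 6.62% and 5.08%, Cd40lg 2.94% and 2%). These percentages do not take off the DP WT level, which for Ccr7, at 6.29 to 9.39 CPM, took in that of DP KO replicate 2 (8.19 CPM). Genes chosen for their CD4 against DP difference in 1 WT replicate kept 0.37 to 0.39 of it in KO in the other replicates, and genes chosen in 1 KO replicate had a WT difference 1.21 to 1.48 times the KO one, so selection of genes by their WT difference is argued against. Of the first set 3.2% to 4.7% had a KO difference at or above that in WT, under the 5% that mixing of both cell types in equal shares for all genes predicted. A real loss of distance would shrink the difference of nearly all genes as well, so this share cannot tell the 2 apart. Mixing in equal shares could bring no more DP KO cells into CD4 KO than Cd8a allows, 9.11% to 10%, but that is 1 gene on which a sort gate can act. Partial mixing of the sorts therefore remains open for this pattern, although it would not account for the genes above. A loss of the distance between the stages when Satb1 is removed is a biological hypothesis that the design allows and these tests do not establish.

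The third pattern is the Satb1 count left in KO, 67.5% of WT in DP and 45.8% in CD4. If it came from cells with an intact gene, these would bring their WT level of other transcripts too, so that hardly any gene would lie below that share by more than its spread. By edgeR, with the lowest share of Satb1 (lowest KO over highest WT library, 63.1% in DP and 41.8% in CD4) as the bound, 140 of 7441 genes abundant in WT did so in DP and 70 of 7526 in CD4 (adjusted p under 0.05), which argues against intact cells as the whole source in both cell types. Of the same genes 15 in DP and 18 in CD4 stood under 10% of WT, less than a larger share of intact cells would bring. These are the lowest of many genes, and their spread was not tested against that level. This form was chosen after 2 earlier ones had left CD4 open: a bound at 5% of the genes gave 6.24% in DP and 3.35% in CD4, and a t test with 4 degrees of freedom gave 46 genes in DP and 0 in CD4 (246 and 137 at an unadjusted p under 0.05). Transcripts of a deleted allele stay open, since the tables hold totals per gene and reads from exons outside the deleted part were not tested.

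Other splits of the same libraries were tried with edgeR for each count. For KO against WT the real split called 5179 genes in DP and 6868 in CD4, and CD4 WT against DP WT called 9573, with 0 calls as the highest of the other splits in each case, 1 of 10 splits being as large. With 10 splits the share cannot fall under 0.05. Among the 4 splits that part all 3 same-numbered pairs the highest other was 0 as well. For the interaction 1 of 100 drawn splits, the real one with 5088 calls, was as large, and the highest other had 2800. The others mix KO and WT libraries in at least 1 cell type. They thus ask whether the genotype labels matter at all, not whether the effects are equal in DP and CD4. The low share bears only on labels drawn without regard to the pairs, and no conclusion on equal effects is drawn from it. Of the 32 splits that part all pairs in both cell types 2 were as large, a share over 0.05, so chance cannot be excluded among these. The other of the 2, with 7734 calls, is the real split with the labels of CD4 turned, which adds the effects of both cell types instead of setting them apart, and the next had 2800. That turned split was not among the 100 drawn.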

How the results depend on the processing

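The runs with DP WT replicate 3 as the lone control and without sex chromosome genes were chosen after seeing the data. Of 209 results for named genes 201 were called, 183 of them under every alternative run, 18 lost the call under at least 1, and 4, none of them called, changed direction. The losses fell on leaving out a library (64 values), a single control (5), no low-count filter (7), 1 model over all libraries (2, Cd8a and Cd79b in DP, adjusted p = 0.106 and 0.0862), the replicate block (2) and limma-voom (2). No low-count filter ended the interaction calls of Ccr7, Cd40lg, Gzma, Pyroxd2, Rn18s-rs5, Rn7s1 and Rn7s2 (adjusted p = 0.0547 to 0.106). DESeq2, its size factors and a mean count of at least 10 lost none. In each case the cause was not tested, apart from the fewer libraries of a left-out fit.

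Counts of called genes stayed within 1.5 times of the value given under DESeq2, its size factors, limma-voom, no filter, the replicate block and each left-out library. They moved with a minimum absolute log2 fold change of 1, by construction: to 856 higher and 1153 lower in DP, 1424 and 968 in CD4, 2391 and 2019 for CD4 WT against DP WT and 1462 and 862 for the interaction. With the lone control, whose spread is assumed to be that of the other libraries, DP counts were 1159 and 877, with fewer samples as 1 cause. Without sex chromosome genes they were 2716 and 2322.

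List calls moved more. With an estimated correlation 0 lists were higher and 0 lower in each cell type, where at an unadjusted p under 0.05 camera had 1 (DP stage genes, lower) in DP and 2 (DP stage genes, higher, and receptor signalling components, lower) in CD4, and fry called 4 higher and 3 lower in DP and 4 and 8 in CD4. With the replicate block 8 lists were higher in DP instead of 5. Leaving out 1 library gave 2 to 8 higher and 2 to 5 lower in DP, with the lowest values without DP KO replicate 2. The block ended 2 calls of named genes (Oas1a in DP, Cd40lg in the interaction) and no other. In CD4 it added the erythroid list as higher (adjusted p = 0.0375) and the ribosomal list as lower (0.0246).

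The 4 genes that changed direction had values near 0 or few counts. Zbtb7b in DP (-0.31) ran from -2.391 without KO replicate 2, where it was called (adjusted p = 0.0214), to 0.229 without KO replicate 3, with 0.113 and 0.138 without KO replicate 1 and WT replicate 1, and 0.216 with the lone control. Ccr7 in DP was called only without KO replicate 2 (-1.74, adjusted p = 0.000374). Cd40lg in DP (0.09) was -0.32 with the block, -0.384 with limma-voom, -0.01 with the lone control and -1.247 to 0.517 with a library left out. In CD4, Il7r (0.02) ran from -0.035 to 0.091 and Itgb7 (-0.06) from -0.098 to 0.004. In the simulation the interaction recovered 37.9% of planted changes of 2 times. Far fewer genes were planted than were called in the data, so recovery there can be higher. A missing call is still no evidence of equal effects.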

Other observations

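Further lists did not pass, and the calls among their members are given here over all genes, with those adjusted over the list alone in parentheses. In DP KO the T lineage transcription factors had 5 higher and 5 lower of 18 (5 and 5), among them Gata3, a driver of the CD4 lineage, which rose from 111 ± 4.49 to 353 ± 29.6 CPM, and Bcl6 and Myb, which fell by 1.83 and 0.87 on the log2 scale. The CD4 lineage list had 2 higher and 4 lower of 9 (2 and 4), the response genes of the T cell receptor 3 and 3 of 14 (3 and 3), regulatory T cell genes 5 and 2 of 16 (6 and 3), DN thymocyte genes 4 and 1 of 12 (4 and 1), p53 targets 2 and 4 of 12 (3 and 4), with Fas at -1.01, and immediate early genes 0 and 2 of 14 (0 and 2). Chemokine and homing receptors had 5 and 5 of 16 (5 and 5), with Ccr9, a thymus homing receptor, falling from 869 ± 46.3 to 149 ± 20.9 CPM, and a median of -0.12 beside a mean of 0.33. In CD4 KO the transcription factors had 7 higher and 8 lower of 18 (7 and 8), Id2 falling by 1.38. There CD8 lineage and cytotoxic genes had 5 and 3 of 17 (5 and 4), with Gzma rising from 7.39 ± 2.83 to 132 ± 19.4 CPM, innate-like genes 3 and 5 of 11 (3 and 6), DN thymocyte genes 6 and 1 of 13 (6 and 1), with Kit at 1.62, p53 targets 2 and 4 of 12 (2 and 4), immediate early genes 0 and 2 of 15 (0 and 0, and 2 and 1 with the replicate block) and ribosomal protein genes 6 and 17 of 230 (3 and 6). With the block the ribosomal genes had 7 higher and 50 lower, and their list passed as lower (adjusted p = 0.0246).

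Markers of other cell types showed few changes. B cell markers had 1 higher and 1 lower of 9 in DP (1 and 2 with the block) and 2 and 0 in CD4, where Cd79b rose from 3.53 ± 1.59 to 17.4 ± 0.333 CPM. Cd79b also stood at 15.3 ± 1.37 CPM in DP WT. Myeloid and dendritic markers had 0 and 1 of 11 in DP and 1 and 0 in CD4, and stroma markers 1 and 1 of 6 in DP, with Epcam at -1.84, and 0 and 2 of 7 in CD4 (1 and 3 with the block). Erythroid markers and sex-linked transcripts had 0 called of 5 each in both cell types by edgeR, while with the replicate block the erythroid markers had 5 higher in DP (list adjusted p = 0.0066) and 4 in CD4 (0.0375), and 1 sex-linked transcript was lower in DP and 1 higher in CD4. Of the mitochondrially encoded genes on chromosome M, 1 of 16 was lower in DP and 0 in CD4, and the 2 met by the fixed pattern were not called.

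With the replicate block the immediate early genes also passed in DP, as lower (adjusted p = 0.0453). Xist was near 0 in DP WT replicates 1 and 2 only, while Ddx3y, on chromosome Y, was at 39.4 to 125 CPM in all 12 libraries.

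The genes lowest in CD4 KO were not equally low in its libraries, a point chosen after the values were seen. As a percentage of the WT mean, KO replicates 1, 2 and 3 had 6.59, 5.84 and 1.16 for Als2cl, 4.97, 3.89 and 0.388 for Tmie, 5.17, 5.1 and 0.782 for Slc15a1, 5.78, 4.67 and 0.487 for Pyroxd2, and 6.45, 6.02 and 1.32 for Tspan9. Als2cl and Tmie are neighbours on chromosome 9, from 110880120 to 110900530 and from 110865687 to 110880073 of mm10, on opposite strands and without overlap.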
